A study of Mus musculus with 19 samples.

How the data were processed

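Total RNA from mouse bone marrow cells was extracted with ISOGEN II, labelled with biotin using a WT Terminal Labeling kit and hybridized to Affymetrix Mouse Gene 1.0 ST arrays, per the labels and the header of the probe table. There were 19 arrays in 9 groups. The groups were normal marrow (normal, n = 2), marrow infected with an empty vector (vector, n = 2), with IDH2/R140Q (I, n = 2), with NPMc and IDH2/R140Q (NI, n = 2), with these and DNMT3A/R882H (NID, n = 2), with these and FLT3-ITD instead (NIF, n = 2), and with all 4 (NIDF, n = 2). The remaining groups were leukaemia cells that were made with all 4 mutations, of which IDH2/R140Q could be excised (AML, n = 2), and the same leukaemia after deletion of IDH2/R140Q (IDH2-deleted AML, n = 3). NPMc is the cytoplasmic mutant form of NPM1. The labels call the samples biological replicates and give no animal, day or litter, so every p-value here measures only the spread between these samples. The species and sequence of the introduced gene copies are not given in the sources used here.

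The deposited values were log2 signals for 28856 probe sets, between 4.34 and 14.3, with no missing value, and log2 was read from that range. The software and the background, normalization and summary methods used by the authors are not given in the sources used here. Exact ties between arrays and array medians were read as 3 separate normalization runs of the deposited table. The 5 AML arrays shared 1081 to 2023 tied values per pair (array medians 7.47 to 7.58). The 4 normal and I arrays shared 26 to 46 (medians 7.14 to 7.24), and the 10 vector, NI, NID, NIF and NIDF arrays shared 1 to 9 (medians 7.83 to 7.93). Of 110 pairs of arrays from different runs, 3 had any tie and none had more than 1. The lowest count within the third run is thus as low as the highest between runs, and this run rests on its medians more than on ties. Comparisons of I with vector, NI with I, vector with normal and AML with normal cross these runs as read here, so in them the run and the group cannot be told apart.

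Of the probe sets, 21789 carried 1 gene symbol, 1621 several and 5446 none. Only those with 1 symbol were used, and for the 999 genes with more than 1 probe set the one with the highest mean over all arrays was taken, which left 19938 genes. Gene identifiers matched the reference table for 21698 symbols and did not for 91, and 0 symbols changed. No filter on signal was applied. For arrays, their number limits the precision, and groups of 2 or 3 give wide errors.

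A mean per group was fitted to all 19 arrays with limma 3.58.1 in R 4.3.3 (10 residual and 3.02 prior degrees of freedom), with limma's moderated test, two-sided, and Benjamini-Hochberg adjustment over all genes within a comparison. Genes with an adjusted p under 0.05 are said to have risen or fallen. Changes are log2 differences with the standard error (SE) of that fit, and group values are means with the standard deviation (SD). Each main comparison was also fitted with its own arrays alone, and that adjusted p is called the own-array adjusted p. NI, NID, NIF and NIDF form a balanced design of DNMT3A/R882H by FLT3-ITD, from which both main effects and their interaction were estimated. The comparison of I with normal marrow and the simple effects within that design were added after the runs had been found.

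There were 21 gene lists with 496 entries, of which 453 were measured: Hoxa cluster and cofactors, Hoxb cluster, hypoxia response, glycolysis, stem and progenitor, primary granule, mature granulocyte, monocyte and macrophage, erythroid, B-lineage, T and NK cell, megakaryocyte and platelet, mast cell, basophil and eosinophil, stromal and endothelial, interferon-stimulated, S phase, G2/M phase, STAT5 and MAPK feedback, ribosome biogenesis and Myc, 2-oxoglutarate-dependent dioxygenase, and immediate-early and stress genes. Glycolysis and hypoxia shared 6 measured members, hypoxia and the dioxygenases 6, and hypoxia and monocyte genes 1. Stem genes shared 1 each with the Hoxa, Hoxb and mast cell lists, and the STAT5 and immediate-early lists shared 1. Each list was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 21 lists, and its members were counted over all genes and adjusted over the list alone.

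The groups, comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named, among genes past the threshold whose arrays did not overlap between the groups, the 10 largest rises and falls in the first 3 comparisons and the FLT3-ITD main effect and the 5 largest elsewhere. It left out predicted genes, clones, receptor and immunoglobulin segments and small RNAs. It added Hoxa9, Meis1, Idh2, Npm1, Dnmt3a and Flt3 everywhere, and up to 4 members with the smallest p of each list that passed camera or held 3 or more changed genes. Where fewer than 10 genes passed, the 5 smallest p were named. The rule was changed after the runs were found: NI against vector and I against normal took the places of I against vector and NI against I, and comparisons across runs name only the 6 fixed genes.

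Relations between comparisons were Pearson's r and Spearman's rho across genes, with an exact two-sided test over all reassignments of the arrays within each comparison. Alternatives were quantile normalization, median centring and cyclic loess over all arrays, leaving out the dimmest genes, averaging probe sets or testing each on its own, a variance trend, array weights, a replicate block, own arrays, and leaving out each array. Fits with the arrays of 1 run were added later. A fit without 1 array of a pair assumes that the lone array varies like the other groups.

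The fit was tested on simulated data with 200 changed genes in each of 5 draws. Changes of 0.5, 1 and 2 on the log2 scale were recovered in 62.7%, 90.7% and 98.5% of genes for IDH2-deleted AML against AML, in 56.7%, 91.6% and 98.2% for NI against vector, and in 52.2%, 91.3% and 99.1% for I against normal. For the same sizes the FLT3-ITD main effect gave 80.6%, 95.8% and 100%, the DNMT3A/R882H main effect 81.8%, 97.0% and 99.7%, the interaction 26.9%, 83.6% and 97.6%, and NIDF against NI 53.7%, 91.6% and 98.8%. Unchanged genes called per draw numbered 7.8 for the deletion, 10 for NI against vector, 10.4 for I against normal, 8.6 for FLT3-ITD, 9.4 for DNMT3A/R882H, 8 for the interaction and 6.6 for NIDF against NI. The variance within IDH2-deleted AML was 4.28 times that of the other groups. Simulated with that spread, the deletion comparison recovered 60.9%, 92.8% and 99.1% and called 63.2 unchanged genes per draw. These are a larger share of its calls than an adjusted p under 0.05 should allow. A hypoxia list shifted by 0.5 was found in 5 of 5 draws, with 9 calls in the 3 lists that share its members and 1 call in the 17 others. Noise was drawn independently for each gene, so these draws give no rate of false lists for real arrays, where genes are correlated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.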

Results

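Gene expression was measured in mouse bone marrow cells that carried none, 1 or several of the mutations found together in acute myeloid leukaemia, and in leukaemia cells made with all 4 of them, before and after deletion of IDH2/R140Q. The 19 arrays fell into 9 groups of 2, except for IDH2-deleted AML with 3. The series title concerns cooperation between the IDH2 and NPM1 mutations in activating Hoxa9, Meis1 and hypoxia pathways. Array medians lay between 7.14 and 7.93 on the log2 scale and grouped by normalization run. Within groups the correlation between arrays was lowest in IDH2-deleted AML, at 0.984 to 0.992, against 0.997 between the AML arrays.

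Hoxa9 and Meis1, a homeobox gene and its cofactor that keep progenitors self-renewing, were low in normal marrow and high in AML. Hoxa9 (probe set 10544788) averaged 7.18 ± 0.07 (SD, n = 2) in normal marrow, 6.89 ± 0.19 in I, 7.58 ± 0.13 in vector, 9.66 ± 0.32 in NI, 9.90 ± 0.22 in NID, 9.54 ± 0.30 in NIF and 10.72 ± 0.05 in NIDF. It was 10.87 ± 0.13 (n = 2) in AML and 10.09 ± 0.47 (n = 3) after deletion of IDH2/R140Q. Meis1 (probe set 10384504) averaged 8.06 in normal, 8.15 in I, 8.30 in vector, 9.0 in NI, 9.80 in NID, 8.86 in NIF, 10.04 in NIDF, 10.71 in AML and 9.10 in IDH2-deleted AML. Egln3, an oxygen-sensing prolyl hydroxylase that hypoxia induces, averaged 8.84 in normal, 9.93 in I, 9.17 in vector, 10.49 in NI, 11 in AML and 9.81 in IDH2-deleted AML. Levels are comparable only within a normalization run.

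**Figure D1:**
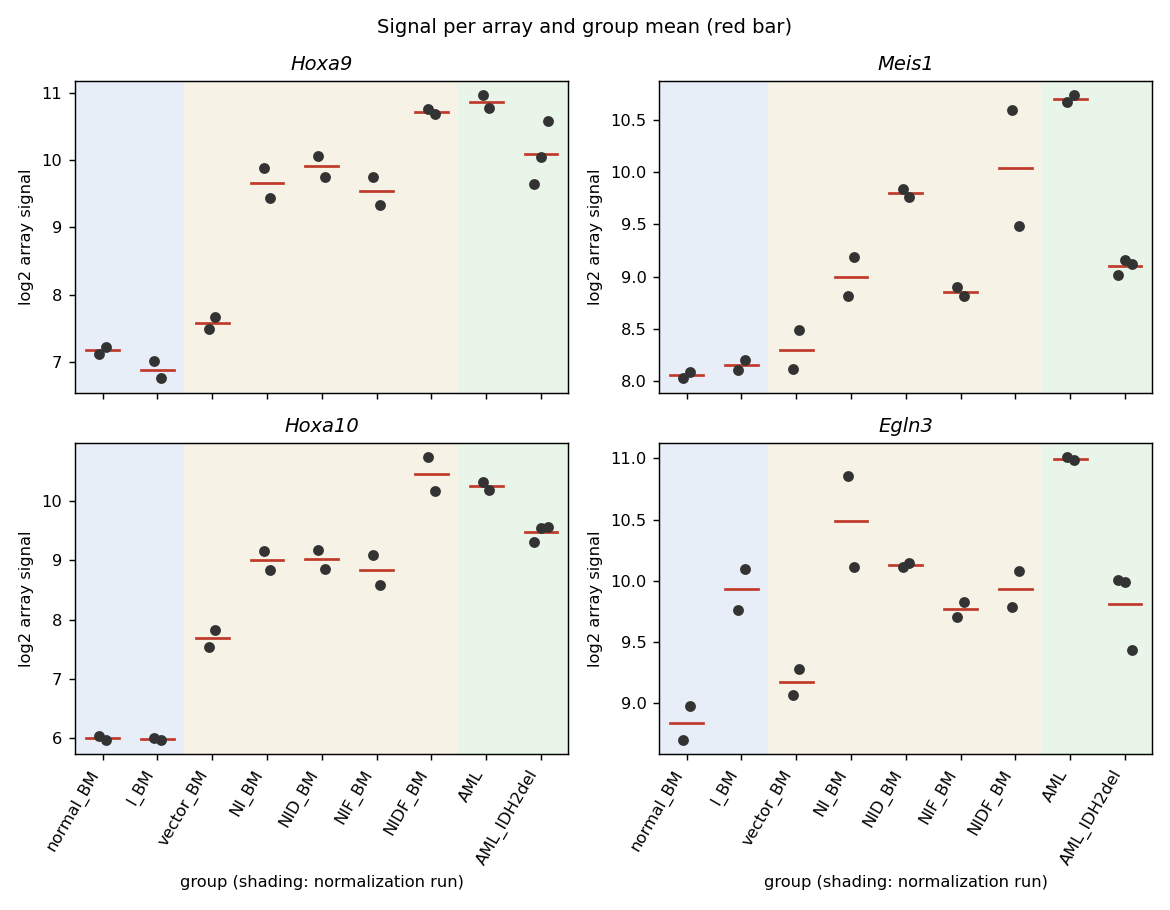
Log2 signal of Hoxa9, Meis1, Hoxa10 and Egln3 on each of the 19 arrays (points) by group, with group means as red bars and shading for the 3 normalization runs. Hoxa9 means rose from 7.58 in vector to 9.66 in NI marrow, and Meis1 means were 10.71 in AML and 9.10 in IDH2-deleted AML.

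The comparison of IDH2-deleted AML with AML asked which genes changed in established leukaemia when IDH2/R140Q was removed. Meis1 fell by 1.61 ± 0.23 (SE, 3 against 2 arrays, adjusted p = 2.2e-04) and was lower in each deleted array, by 1.54 to 1.69 (changes of -1.69, -1.54 and -1.59). Mecom, a stem cell transcription factor, fell by 2.29 ± 0.17 and Kit, the stem cell factor receptor, fell by 1.68 ± 0.12. Hoxa9 fell by 0.78 ± 0.22 (adjusted p = 0.021), with changes of -1.22, -0.82 and -0.29 in the 3 deleted arrays. Its own-array adjusted p was 0.22, and its adjusted p became 0.15 and 0.065 without AML replicates 1 and 2, and 0.069 and 0.0505 without deleted replicates 1 and 2. Of 12 measured Hoxa cluster genes and cofactors, 9 fell and 0 rose (10 fell adjusted over the list alone), among them Hoxa11 at -1.44, Hoxa10 at -0.79, Hoxa4 at -0.59 and Hoxa2 at -0.57. The list median was -0.69 (camera adjusted p = 2.0e-04, and adjusted p = 0.28 with an estimated correlation). None of the 9 Hoxb genes passed, over all genes or over the list alone, and their median of -0.08 and mean of 0.10 differed in sign (camera adjusted p = 0.79).

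Genes of immature myeloid cells fell with Meis1. Of 23 stem and progenitor genes, 9 fell and 4 rose, with the same counts adjusted over the list alone, a median of -0.20 and a camera adjusted p of 0.048 (adjusted p = 0.20 with an estimated correlation). Besides Mecom and Kit, Hlf was at -1.29, and Cd34, the progenitor surface antigen, fell by 2.68 ± 0.48 with an own-array adjusted p of 0.13. Of 14 primary granule genes, which mark promyelocytes, 12 fell and 0 rose (12 and 1 adjusted over the list alone), including the serine protease Prss57 at -1.93, Ms4a3 at -1.14, Gfi1 at -1.11 and cathepsin G, Ctsg, at -0.72. Their median was -0.69 (camera adjusted p = 3.9e-06, and adjusted p = 0.12 with an estimated correlation). Ribosome biogenesis and Myc targets fell in 18 of 25 (23 over the list alone), for example Wdr12 at -1.05, Polr1b at -0.73 and nucleolin, Ncl, at -0.67, and Myc, on the STAT5 list, was at -1.32. G2/M genes fell in 9 of 24 (13 over the list alone), such as Cdca8 at -0.58 and Cdc20 at -0.50, and S phase genes in 6 of 24 (5 over the list alone), such as Mcm6 and Dtl at -0.67 each. These 3 lists had medians of -0.48, -0.38 and -0.27 and passed camera at 1.8e-08, 2.3e-05 and 0.0027, with adjusted p = 0.28, 0.47 and 0.57 with an estimated correlation.

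Hypoxia-response genes moved both ways on deletion. Of 39, 8 fell, including Ak4 at -2.56 and Egln3 at -1.19, and 6 rose, including the collagen-modifying enzymes Lox at 3.37 and Plod2 at 2.81 and the haem-degrading enzyme Hmox1 at 2.27. Adjusted over the list alone, 9 fell and 8 rose, and the list did not pass camera (median 0.03, adjusted p = 0.79). Of the named rises, Hmox1 is also on the monocyte and macrophage list, and Lox and Plod2 modify collagen, whose genes Col1a1 and Col1a2 rose as well. These rises cannot be told apart from the rises in genes of other cell types given below. Glycolysis genes fell in 9 of 17 with 0 rises (9 and 1 over the list alone), among them Aldoc at -1.13, Pfkl at -0.63, Pfkm at -0.62 and Hk3 at -0.60, with a median of -0.23 (camera adjusted p = 0.0081, and adjusted p = 0.28 with an estimated correlation). Of 27 2-oxoglutarate-dependent dioxygenases, the enzyme class that the product of mutant IDH2 inhibits, 3 fell and 2 rose, with the same counts over the list alone. Tet1, a DNA demethylase, fell by 1.5 ± 0.15 and Plod1 rose by 0.81, and the list median was 0.01 (camera adjusted p = 0.86).

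The largest rises on deletion were mostly in genes of other cell types of the marrow. Of 17 stromal and endothelial genes, 14 rose and 2 fell, with the same counts over the list alone, led by the matrix genes Sparc at 4.61 ± 0.27, Col1a1 at 4.18 and Col1a2 at 4.12, and Dcn, outside the list, rose by 4.52. Monocyte and macrophage genes rose in 24 of 28 (25 over the list alone), including the antigen-presenting genes H2-Aa at 3.74, Cd74 at 3.43 and H2-Ab1 at 3.36. Their median was 2.0 (camera adjusted p = 1.6e-22), and this was the 1 list that also passed with an estimated correlation (adjusted p = 0.017). Among B-lineage genes 15 of 21 rose (18 over the list alone), such as Cd79a at 3.88, Ms4a1 at 3.79 and Il7r at 3.56. T and NK cell genes rose in 17 of 21, with 1 fall (18 and 1 over the list alone), such as Ccl5 at 2.71, and erythroid genes in 14 of 21 (18 over the list alone), such as Alas2 at 3.30, the first enzyme of haem synthesis, and carbonic anhydrase Car2 at 4.67 ± 0.58. Interferon-stimulated genes rose in 19 of 24 (20 over the list alone), such as Ifi27l2a at 2.58 and Irf7 at 2.39, and immediate-early genes in 12 of 17 (13 over the list alone), such as Jun at 1.25 and Nr4a1 at 0.92. Camera adjusted p were 8.1e-09 for stromal, 5.4e-13 for B-lineage, 4.7e-11 for T and NK, 1.0e-08 for erythroid, 4.1e-14 for interferon and 1.9e-06 for immediate-early genes, and these calls were lost with an estimated correlation, with adjusted p of 0.12, 0.16, 0.20, 0.28, 0.16 and 0.20 in that order.

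Smaller movements were seen in the remaining lists on deletion. Mature granulocyte genes rose in 5 of 25 (4 over the list alone), such as Il1b at 3.74 and the collagenase Mmp8 at 1.26, with a median of 0.22 (camera adjusted p = 0.0023, and adjusted p = 0.57 with an estimated correlation). STAT5 and MAPK feedback targets rose in 7 and fell in 2 of 27 (8 and 2 over the list alone), with Socs2 at 1.62, Etv5 at 0.53 and Bcl2l1 at 0.50 (median 0.15, camera adjusted p = 0.027, and adjusted p = 0.21 with an estimated correlation). Megakaryocyte genes rose in 6 and fell in 1 of 15 (6 and 2 over the list alone), with Ppbp at 2.37 and Itga2b at -0.61 (camera adjusted p = 0.054). Mast cell, basophil and eosinophil genes rose in 3 and fell in 5 of 19, with the same counts over the list alone, such as the protease Mcpt4 at 1.48 and Gata2 at -1.68, and their median of 0.05 and mean of -0.12 differed in sign (camera adjusted p = 0.79). Other large falls were in Cyp11a1 and Mc5r at -2.74 each, Epha7 at -2.41, the deiodinase Dio2 at -2.33, Myct1 at -2.28, Rab38 at -2.22 and Muc13 at -2.20. Rtp4, Slc4a1, Car1 and Ifit3 rose by 3.99, 3.84, 3.83 and 3.80.

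In total 5253 of 19938 genes passed on deletion, 2334 up and 2919 down, of which 732 rose and 150 fell at least 2-fold. Simulated with the larger spread of the deleted arrays, this fit exceeded its nominal rate of false calls. These counts and the list counts on deletion can thus be too high. With the 5 AML arrays alone the count was 868 (422 up and 446 down), and 48 of the 91 named genes that passed also passed there. Meis1, Mecom, Kit, Sparc, Cd79a and H2-Ab1 were among these (own-array adjusted p = 0.015 to 0.026), whereas Hoxa2, Hoxa4, Hlf, Gfi1, Ctsg, Egln3, Plod2, Pfkl, Hk3, Polr1b, Wdr12, Ncl, Socs2, Etv5, Ppbp, Car1, Car2, Slc4a1, Ifit3 and the cell-cycle genes were not. The count was 3104 without AML replicate 1 and 2990 without AML replicate 2.

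The comparison of NI with vector marrow asked what NPMc and IDH2/R140Q did together. No group carried NPMc alone, and I marrow lies in another run, so the part of each mutation cannot be told apart. Hoxa9 rose by 2.08 ± 0.25 (2 against 2 arrays, adjusted p = 4.0e-04), Hoxa5 by 2.01 ± 0.27, Hoxa6 by 1.65 ± 0.23 and Hoxa10 by 1.31 ± 0.20. Of 12 Hoxa genes and cofactors 5 rose (8 over the list alone) and 0 fell. Meis1 was at 0.70 ± 0.25 and did not pass (adjusted p = 0.13), though its own-array adjusted p was 0.039 and it passed with array weights (adjusted p = 0.037). The list median was 0.69 (camera adjusted p = 6.0e-07, and adjusted p = 0.22 with an estimated correlation). Hoxb genes did not pass (median 0.26, camera adjusted p = 0.36).

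Hypoxia-response and glycolysis genes rose in NI marrow. Of 39 hypoxia genes 9 rose and 0 fell (14 and 1 over the list alone), including Egln3 at 1.31 ± 0.23, Bnip3, a mitophagy receptor, at 1.15 ± 0.18, hexokinase Hk2 at 0.96 ± 0.17 and aldolase, Aldoa, at 0.36. Of 17 glycolysis genes 7 rose and 0 fell (10 and 1 over the list alone), including Pfkp at 0.63 and Pgam1 at 0.51. Dioxygenase genes rose in 5 of 27 (8 over the list alone), including the collagen hydroxylase P4ha1 at 0.89, Tet2 at 0.55 and Egln1 at 0.49. The 3 lists had medians of 0.30, 0.39 and 0.17 with camera adjusted p of 1.4e-05, 1.5e-05 and 7.4e-04, and an adjusted p = 0.22 each with an estimated correlation. The own-array adjusted p of these genes was under 0.05, but Egln3 had an adjusted p of 0.072 without vector replicate 1 and 0.072 without NI replicate 1, Hk2 had 0.065 and 0.051, and P4ha1 had 0.12 and 0.14, and 0.085 without vector replicate 2.

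Genes of the B lineage and some genes of other lineages fell in NI marrow. B-lineage genes fell in 16 of 21 (18 over the list alone), such as Ms4a1 at -3.92, Cd79a at -3.39, Cd22 at -2.86 and Cr2 at -2.70, and outside the list Jchain was at -3.85, Fcer2a at -3.53 and Fcmr and Cd72 at -3.29 each. T and NK genes fell in 7 of 21 (9 over the list alone), such as Cd2 at -2.47, and megakaryocyte genes in 4 of 15 (4 over the list alone), such as the platelet chemokines Ppbp at -3.40 and Pf4 at -1.97. Monocyte and macrophage genes fell in 10 and rose in 1 of 28 (12 and 7 over the list alone), with H2-Ab1 at -2.44, the complement gene C1qb at -2.42 and Axl at -1.97 against Cd14, the endotoxin co-receptor, at 2.08. That list had a median of 0.08, a mean of -0.47 and a downward test (camera adjusted p = 1.1e-04). Of the 21 erythroid genes, 0 passed limma over all genes in the fit to all arrays, and 5 fell over the list alone. The erythroid median was -1.24, with Trim10 at -1.46 and Epor, the erythropoietin receptor, at -1.26 (adjusted p = 0.096 and 0.068). Camera adjusted p were 1.1e-33 for B-lineage, 1.5e-12 for T and NK, 4.9e-05 for megakaryocyte and 1.3e-11 for erythroid genes, and with an estimated correlation the B-lineage list had an adjusted p of 0.058 and the other 4 lists 0.22.

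Among the other lists in NI marrow, primary granule genes rose in 4 of 14 (5 over the list alone), with Gfi1 at 0.74, Cebpa at 0.65, Prtn3 at 0.46 and Igsf6 at 0.31 (median 0.27, camera adjusted p = 4.1e-04, and adjusted p = 0.22 with an estimated correlation). Interferon genes rose in 2 of 24 (2 over the list alone), Dhx58 at 0.74 and Mx1 at 0.68 (camera adjusted p = 0.013, and adjusted p = 0.54 with an estimated correlation). S phase and G2/M genes had medians of -0.25 and -0.15 with no gene past the threshold (camera adjusted p = 2.6e-06 and 4.7e-05, and adjusted p = 0.34 and 0.43 with an estimated correlation). Ribosome genes had a median of -0.24, with Odc1 at -0.77 the 1 of 25 that fell and 0 over the list alone (camera adjusted p = 1.5e-06, and adjusted p = 0.34 with an estimated correlation). Mast cell genes, with 1 of 19 down (1 up and 2 down over the list alone), Slc6a4 at -0.44, and stromal genes, with 0 of 17 (2 down over the list alone), had medians of -0.40 and -0.19 (camera adjusted p = 0.0041 and 0.013, and adjusted p = 0.22 and 0.34 with an estimated correlation). Not passing camera were the stem list (1 up, 2 down of 23, 2 and 2 over the list alone, with Kit at 0.51, Slamf1 at -1.42 and Pdzk1ip1 at -1.39, median 0.23, mean -0.01, test downward, adjusted p = 0.55), mature granulocyte genes (1 up of 25, 1 over the list alone, adjusted p = 0.44), immediate-early genes (2 up of 17, 5 up and 1 down over the list alone, adjusted p = 0.11) and STAT5 targets (adjusted p = 0.070). The STAT5 list had 1 rise and 4 falls, as over the list alone, a median of 0.04 and a mean of -0.11, with Il2ra at -2.58, Socs2 at -1.32, cyclin Ccnd1 at -1.10 and Pim2 at -0.71. Rises outside the lists included Cstdc6 at 3.48, Penk at 2.45, Stfa2 at 2.23, Dnah12 at 2.14, Dpep2 at 1.88 and Kcnj2 at 1.75, and the desaturase Scd1 was at -3.83. The Y-linked genes Eif2s3y and Uty were at -4.32 and -3.40.

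NI differed from vector marrow in 1089 genes, 568 up and 521 down, with 24 up and 233 down at least 2-fold. The own-array fit gave 2642 and contained all 59 named genes that passed. It also held 22 named genes that had not passed with all arrays in the fit. Leaving out vector replicate 1 or 2 gave 259 or 287 genes, and leaving out NI replicate 1 or 2 gave 277 or 404.

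**Figure D2:**
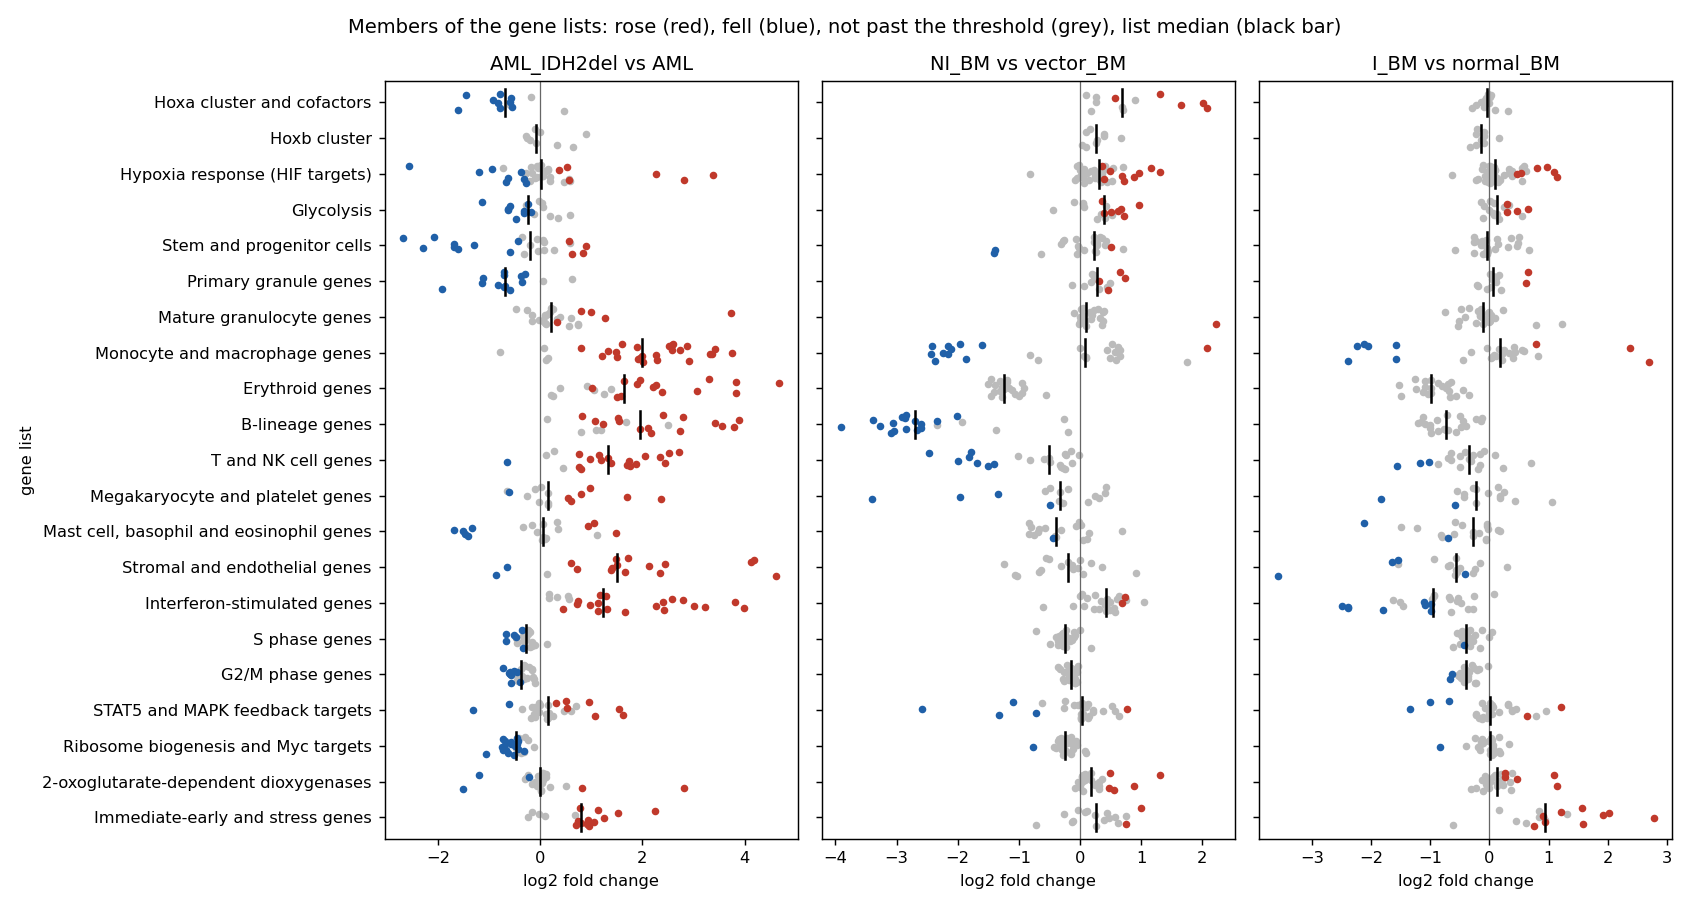
Log2 change of each measured member of the 21 gene lists (points) in IDH2-deleted AML against AML, NI against vector and I against normal marrow, with members that rose in red, members that fell in blue, others in grey and list medians as black bars. Monocyte genes had a median of 2.0 in the first panel, B-lineage genes -2.70 in the second and interferon genes -0.95 in the third.

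I was compared with normal marrow to see IDH2/R140Q alone within 1 run, where infection also differed. Sex-linked genes differed too, in I replicate 1, as given below. Immediate-early and stress genes rose in 9 of 17 (13 up and 1 down over the list alone), including the transcription factors Jun at 2.77 ± 0.15, Fos at 2.02, Nr4a1 at 1.58 and Atf3 at 1.56 and the chaperone Hspa1a at 1.93 (median 0.93, camera adjusted p = 2.0e-13, and adjusted p = 0.16 with an estimated correlation). Outside the lists, rises included Cxcl2 at 2.99, Dnah12 at 2.75, Dpep2 at 2.49, Ptgs2 at 2.44 and Ccl3 at 1.78, of which Dpep2 came with an own-array adjusted p of 0.069. Hypoxia genes rose in 6 of 39 (9 over the list alone), among them P4ha1 at 1.15 ± 0.18, Egln3 at 1.09 ± 0.23, Ankrd37 at 0.97 and Bnip3 at 0.81. Glycolysis genes rose in 4 of 17 (6 over the list alone), such as Pfkl at 0.66 and Pfkp at 0.47, and dioxygenases in 5 of 27 (9 over the list alone), such as Kdm3a at 0.46 and Jmjd6 at 0.26. Their camera adjusted p were 1.1e-04, 2.9e-04 and 2.7e-04, with medians of 0.10, 0.12 and 0.13, and adjusted p = 0.44, 0.27 and 0.25 with an estimated correlation. Of the named hypoxia genes only Egln3 also had an own-array adjusted p under 0.05, at 0.034, against 0.082 for P4ha1 and 0.055 for Bnip3, and the glycolysis genes had 0.079 for Pfkp and 0.087 for Pfkl. Egln3 did not pass without normal replicate 1 (adjusted p = 0.17) or I replicate 2 (0.18), nor did Bnip3 (0.20 and 0.24), and P4ha1 was at 0.067 without normal replicate 1.

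Interferon-stimulated genes fell in 8 of 24 in I marrow (17 over the list alone), such as Oasl2 at -2.49, Rsad2 at -2.39, Rtp4 at -2.39 and Mx2 at -0.99, and Oas2 and Oas3, outside the list, were at -2.49 and -2.40. The list median was -0.95 (camera adjusted p = 4.1e-12, and adjusted p = 0.25 with an estimated correlation). Stromal genes fell in 4 of 17 (6 over the list alone), including Sparc at -3.58 and Col1a2 at -1.65 (median -0.56, camera adjusted p = 1.3e-05, and adjusted p = 0.25 with an estimated correlation). Monocyte genes fell in 6 and rose in 3 of 28 (6 and 4 over the list alone), with C1qc at -2.24, Axl at -2.13 and Vcam1, a macrophage and stromal adhesion gene, at -2.39, against the proteoglycan Vcan at 2.70 and Cd14 at 2.37. Their median of 0.19, mean of -0.07 and upward test differed in sign (camera adjusted p = 0.85). T and NK genes fell in 3 of 21 (5 over the list alone), such as Ncr1 at -1.57, mast cell genes in 2 of 19 (3 over the list alone), with Ccr3 at -2.12, G2/M genes in 2 of 24 (18 over the list alone), with Nusap1 at -0.67, and S phase genes in 1 of 24 (2 over the list alone), with Slbp at -0.44. Camera adjusted p were 0.0013, 0.0018, 6.2e-09 and 4.6e-06, and adjusted p = 0.56, 0.27, 0.44 and 0.47 with an estimated correlation.

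Hoxa genes did not pass in I marrow. Hoxa9 was at -0.29 ± 0.25 and Meis1 at 0.09 ± 0.25 (adjusted p = 0.58 and 0.89), and the list median was -0.04 (camera adjusted p = 0.84). Erythroid and B-lineage genes had medians of -0.98 and -0.73 with no member past the threshold (camera adjusted p = 6.8e-05 and 8.3e-05, and adjusted p = 0.56 and 0.47 with an estimated correlation). Primary granule genes rose in 2 of 14 (2 over the list alone, camera adjusted p = 0.053), and STAT5 targets rose in 2 and fell in 3 of 27 (3 and 3 over the list alone, camera adjusted p = 0.45), with Egr1 at 1.21, Spred1 at 0.63, Ccnd1 at -1.0 and Bcl2l1 at -0.69. The Hoxb, stem, mature granulocyte, megakaryocyte and ribosome lists did not pass camera either (medians -0.14, -0.04, -0.11, -0.23 and 0.01), and the stem and ribosome means of 0.04 and -0.04 differed in sign from their medians. Tspan8 and Lipo3 were at -3.11 and -2.20. In all 1030 genes passed, 513 up and 517 down, against 429 (116 and 313) with the 4 arrays of this run alone, where 35 of the 51 named genes that passed also passed. The count was 175 without normal replicate 1 and 170 without I replicate 2.

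Changes in I against normal and in NI against vector fell on many of the same genes. Of the genes that passed, 112 rose in both where 14.6 would be shared by independent lists, 135 fell in both (13.5 by chance), and 3 moved in opposite ways, 1 and 2 in each direction (13.4 and 14.7 by chance). The calls of both comparisons became fewer when any 1 of their arrays was left out, and the shared counts were not taken again in those fits. Genes that rose in both included Egln3, Bnip3, P4ha1, Cd14, Atf3 and Cebpa, and genes that fell in both included Axl, C1qb, Vcam1, Ncr1 and Ppbp. Across genes the log2 changes had r = 0.50 (rho = 0.35), where genes are not independent replicates, and 4 of 36 reassignments of the arrays gave an r as large in size (exact two-sided p = 0.111, the smallest that these arrays can give). The largest other r was 0.441.

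**Figure D3:**
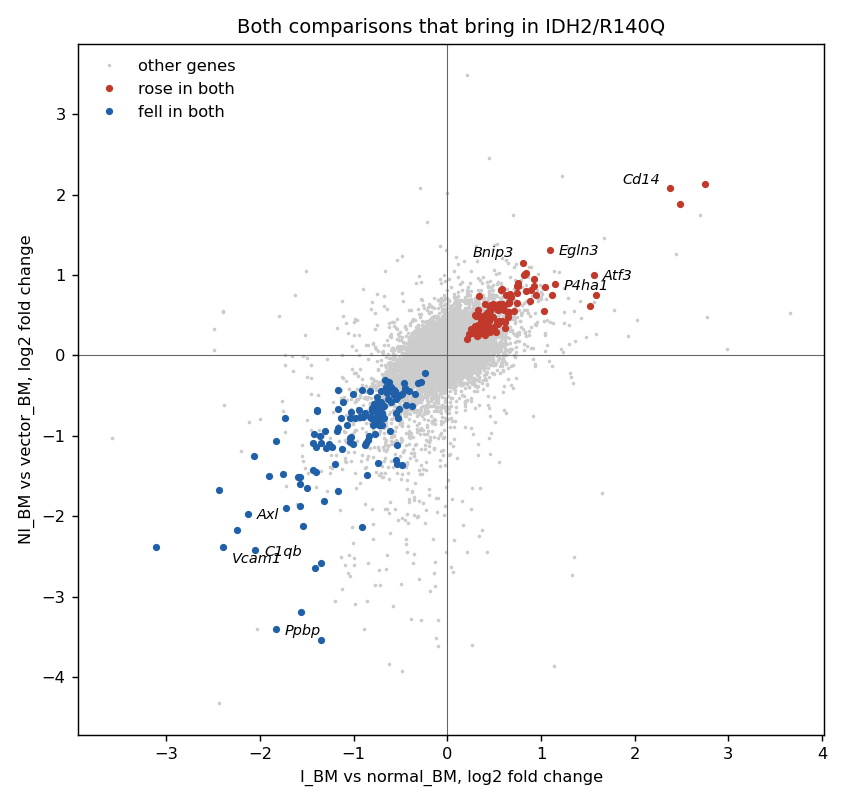
Log2 change of each gene in I against normal marrow (x axis) and in NI against vector marrow (y axis), with the 112 genes that rose in both in red and the 135 that fell in both in blue. Egln3, P4ha1 and Bnip3 lie among the red points and Axl, C1qb and Vcam1 among the blue.

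Gain and loss of IDH2/R140Q were compared to see whether genes moved by its gain in marrow moved the other way on its deletion in leukaemia. Of the genes that rose in I against normal marrow, 167 fell on deletion (75.1 by chance) and 67 rose (60.1), and of those that fell, 164 rose (60.5) and 53 fell (75.7). For NI against vector, 156 of its rises fell on deletion (83.2 by chance) and 90 rose (66.5), and 246 of its falls rose (61.0) and 34 fell (76.3). The planned comparison of I with vector crosses runs: 24 of its rises fell (12.2) and 13 rose (9.72), and 1702 of its falls rose (1960) and 2234 fell (2451). Across genes, r with the deletion was -0.24 (rho -0.14) for I against normal, -0.17 (rho -0.12) for I against vector and -0.26 (rho -0.02) for NI against vector. The exact two-sided p over 60 reassignments of arrays were 0.1, 0.1 and 0.367. Of the 4 relations tested, none passed after Benjamini-Hochberg adjustment (0.148, 0.148 and 0.367 here and 0.148 for the relation of I and NI).

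Within the marrow groups that carried NPMc and IDH2/R140Q, the DNMT3A/R882H main effect compared NID and NIDF with NI and NIF. The signal for Dnmt3a, whose probe set is not known to leave out the introduced copy, rose by 0.89 ± 0.10 (4 against 4 arrays, adjusted p = 0.0034), from means of 8.60 in NI and 8.57 in NIF to 9.62 in NID and 9.33 in NIDF. Rnf217, a ubiquitin ligase gene, rose by 1.33 ± 0.11 and Prrg4 by 0.53 ± 0.07, and the predicted gene Gm10825 fell by 0.94. The next genes, Zfp985 and Mrtfb, were at 0.49 and 0.33 and did not pass (adjusted p = 0.055 and 0.058). All 12 Hoxa genes and cofactors had positive changes, 8 passing over the list alone and 0 over all genes, with Hoxa5 at 1.02, Meis1 at 1.0, Hoxa6 at 0.94, Hoxa10 at 0.82 and Hoxa9 at 0.71 (adjusted p = 0.12, 0.092, 0.092, 0.090 and 0.30). The list median was 0.57 (camera adjusted p = 8.7e-14, and adjusted p = 0.095 with an estimated correlation). Stem genes (median 0.13, 3 over the list alone), ribosome genes (0.18), primary granule genes (0.06) and erythroid genes (-0.70) also passed camera (adjusted p = 1.5e-04, 3.2e-09, 0.045 and 1.9e-05), with adjusted p = 0.054 for stem and 0.83 for the other 3 with an estimated correlation. Limma called 4 genes, 3 up and 1 down, with 1940 at an unadjusted p under 0.05, and with array weights it called 64. The count was 10 without NI replicate 2, 10 without NIDF replicate 1 and 37 without NIDF replicate 2, where Meis1 passed (adjusted p = 1.2e-04), as it did without NIDF replicate 1 (0.026), and Hoxa10 (0.012). Prrg4 did not pass without NI replicate 1, NID replicate 1, NIF replicate 1 or NIF replicate 2 (adjusted p = 0.072, 0.094, 0.072 and 0.085), and Dnmt3a had an own-array adjusted p of 0.052.

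The FLT3-ITD main effect compared NIF and NIDF with NI and NID. The smallest p were for the lipid enzymes Scd2 at 0.49, Lipg at 1.23 and Fdps at 0.41, the steroid enzyme Akr1c18 at 1.49 and the dendritic cell gene Clec9a at -0.67, of which none passed (adjusted p = 0.087 for Scd2 and 0.21 to 0.22 for the others). Hoxa9 was at 0.35, Meis1 at 0.05 and Flt3 at -0.58 (adjusted p = 0.92, 0.98 and 0.92). By camera 14 lists passed, with medians of -0.31 for interferon (Irf7 -0.54), 0.20 for ribosome (Srm 0.39), -0.34 for B-lineage (Ms4a1 -0.79), 0.36 for Hoxa (Hoxa10 0.63, 1 over the list alone), -0.11 for monocyte (H2-Ab1 -0.49), -0.16 for immediate-early (Nr4a1 -0.29, 1 over the list alone), 0.11 for mast cell (Fcer1a 1.36) and 0.30 for Hoxb genes. Dioxygenases (-0.06), hypoxia (-0.05), mature granulocyte (-0.09), S phase (0.13), megakaryocyte (-0.11) and stem genes (-0.07) also passed. Their adjusted p ran from 8.1e-13 to 0.013, and with an estimated correlation none passed (lowest adjusted p = 0.26). Limma called 0 genes, with 985 at an unadjusted p under 0.05 where chance gives 997, and with array weights it called 4. The count was 6 without NI replicate 2, 3 without NIDF replicate 1, 9 without NIDF replicate 2, and 1 each without NID replicate 2, NIF replicate 1 or NIF replicate 2.

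The interaction asked whether DNMT3A/R882H acted differently with FLT3-ITD than without. Outside predicted genes, the smallest p were for Lipg, Rnf217 and Gpnmb at 2.68, 1.45 and 3.15 and for Clec9a and Zfp979 at -1.38 and -1.14, of which none passed (adjusted p = 0.13 for Lipg and Rnf217 and 0.20 for the others). Hoxa10 was at 1.60 ± 0.28 (adjusted p = 0.20). Adding DNMT3A/R882H to NIF raised Hoxa10 by 1.62, Hoxa6 by 1.65 and Hoxa5 by 1.75 (adjusted p = 0.0074, 0.017 and 0.026), while adding it to NI left Hoxa10 at 0.02, without passing. Likewise, adding FLT3-ITD to NID raised Hoxa10 by 1.43 (adjusted p = 0.029), while adding it to NI left Hoxa10 at -0.17, without passing. By camera 9 lists passed, and none with an estimated correlation (lowest adjusted p = 0.083). Limma called 0 genes, with 393 at an unadjusted p under 0.05, and array weights called 5. The count was 13 without NIDF replicate 2, 4 without NI replicate 2, 3 without NIF replicate 1, 2 without NIDF replicate 1, and 1 each without NI replicate 1, NID replicate 1 or NID replicate 2.

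NIDF was compared with NI to see both additions together. Gpnmb, a macrophage glycoprotein gene, rose by 3.0 ± 0.37, Akr1c18 by 2.77 ± 0.36, Lipg by 2.38 ± 0.27, Hoxa10 by 1.45 ± 0.20 (adjusted p = 0.018), Rnf217 by 1.33 ± 0.15 and Scd2 by 0.91 ± 0.09, and the other 2 of the 8 genes that passed were Shtn1 and Fdps, named after their values were seen. Hoxa9 was at 1.06 and Meis1 at 1.04 without passing (adjusted p = 0.28 each). Of 12 Hoxa genes 1 passed over all genes and 9 over the list alone (median 0.95), and of 25 ribosome genes 0 and 16 (median 0.37, with Srm at 0.63), at camera adjusted p of 8.3e-18 and 1.4e-19. Other lists past camera had medians of 0.62 for Hoxb, 0.23 for mast cell, 0.14 for S phase, 0.09 for primary granule, -0.06 for dioxygenase, -0.17 for mature granulocyte, -0.40 for immediate-early, -0.48 for interferon (Irf7 -1.05), -0.48 for B-lineage and -0.54 for erythroid genes. With an estimated correlation none of the 12 lists passed (lowest adjusted p = 0.095, for Hoxa). With the 4 arrays alone 0 genes passed, and Hoxa10 had an own-array adjusted p of 0.55, whereas array weights called 42 genes. The count of 8 was 4 without NI replicate 1, 5 without NI replicate 2 and 48 without NIDF replicate 2, where Meis1 passed (adjusted p = 6.9e-04). Hoxa10 did not pass without NI replicate 1 or 2 or NIDF replicate 1 (adjusted p = 0.071, 0.17 and 0.16), nor did Gpnmb (0.072, 0.0605 and 0.079) or Akr1c18 (0.071, 0.11 and 0.10), and Lipg and Rnf217 were at 0.0605 without NI replicate 2.

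In AML against normal marrow and in NI against I, which cross normalization runs, rescaling did not remove the large differences in Hoxa9. Rescaling acts on whole arrays and not on single probe sets, so the run and the group still cannot be told apart. In AML against normal marrow Hoxa9 was higher by 3.68 ± 0.25, Meis1 by 2.65 ± 0.25 and Dnmt3a by 1.88 ± 0.14, and Hoxa9 stayed at 3.35 to 3.41 and Meis1 at 2.31 to 2.38 after 3 ways of rescaling all arrays. NI exceeded I by 2.77 ± 0.25 in Hoxa9 (2.03 to 2.19 after rescaling). Meis1 was at 0.85 ± 0.25 there, with 0.11 to 0.27 after rescaling, where it did not pass. Hoxa9 in I against vector was at -0.69 (adjusted p = 0.019), but at 0.075 and 0.059 after quantile normalization and median centring. After cyclic loess it was at -0.17, without passing. In vector against normal marrow Hoxa9 was at 0.40 and Meis1 at 0.24 (adjusted p = 0.14 and 0.36). After rescaling, Hoxa9 was at -0.28 to -0.17 and Meis1 at -0.44 to -0.33 there, without passing. The median of all genes was shifted by -0.59 in I against vector, 0.63 in NI against I, 0.57 in vector against normal and 0.29 in AML against normal. Counts past the threshold were 16824, 17213, 17138 and 12689 in that order, which fell to 5949, 6324, 4108 and 7146 after quantile normalization.

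The targeted genes were read as a check of the labels, as far as the mouse probes detect the introduced copies. Idh2 (probe set 10564857) fell by 0.86 ± 0.23 on deletion (adjusted p = 0.016, own-array adjusted p = 0.24), from 11.20 ± 0.09 (n = 2) to 10.34 ± 0.56 (n = 3), and did not pass without AML replicate 1 or 2 or deleted replicate 1 or 2 (adjusted p = 0.065, 0.11, 0.054 and 0.052). Against the AML mean, Idh2 was at -1.28 and -1.08 in deleted replicates 1 and 2 but at -0.22 in replicate 3. Where IDH2/R140Q was added, Idh2 did not pass, at 0.30 in I against normal and 0.17 in NI against vector (adjusted p = 0.58 and 0.77). The probe set is thus not known to read the introduced copy. The fall of Idh2 therefore does not settle the label of any deleted array, least of all that of replicate 3. Npm1 fell by 0.63 on deletion (adjusted p = 0.034, own-array adjusted p = 0.35) and was at -0.71 in NI against vector and -0.57 in I against normal (adjusted p = 0.081 and 0.17). Dnmt3a was at -0.26 and Flt3 at 0.58 on deletion (adjusted p = 0.16 and 0.48). Sex-linked genes differed between groups. Normal marrow had Xist at 5.51 and Eif2s3y at 10.26, I replicate 1 had 12 and 5.20 against 6.34 and 10.44 in I replicate 2, and vector had both high at 12.34 and 9.50. Every array of the NPMc and AML groups had Xist of at least 12 and Eif2s3y of at most 5.24.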

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

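The tests of other splits of the arrays were planned, and no test in this part was chosen after its result was seen. The effect of DNMT3A/R882H differed between marrow with and without FLT3-ITD in 9 gene lists, by camera on the interaction over 8 arrays. The largest such difference was in the Hoxa cluster and cofactors, whose median effect was higher by 0.76 with FLT3-ITD (camera adjusted p = 2.9e-18, and adjusted p = 0.083 with an estimated correlation), with 5 of 12 members passing over the list alone and 0 over all genes, and Hoxa10 at 1.60. Hoxb genes differed by 0.75 (1.4e-05, and 0.25 with an estimated correlation), primary granule genes by 0.24 (2.3e-07 and 0.086), with Gfi1 at 1.09 (adjusted p = 0.75), and hypoxia genes by 0.10 (0.0077 and 0.61). Immediate-early genes differed by 0.088 (0.0034 and 0.52). Differences in the other direction were found in erythroid genes, at -0.62 (1.8e-04 and 0.64), B-lineage genes, at -0.55 (4.1e-08 and 0.32), megakaryocyte genes, at -0.26 (1.8e-04 and 0.32), and monocyte and macrophage genes, at -0.21 (7.3e-06 and 0.25), with H2-Ab1 at -1.41 (adjusted p = 0.44).

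The 8 arrays of this design can be split into 4 and 4 in 35 ways. These include all 3 real effects, so the other splits of an effect are not all arbitrary. Each split was fitted to all 19 arrays, with the 4 and 4 as the only groups among the 8 and the other groups unchanged. The real counts can thus differ from those of the main fit. For the interaction, 19 of the 35 splits gave as many lists as the real 9, so chance cannot be excluded for that number of lists. The highest other count, 14, came from the FLT3-ITD split and from 1 split that is no real effect. Its real count of 0 genes (highest other 3, in the DNMT3A/R882H split) is reached by all 35 whatever the data. The splits therefore say nothing about its genes. For the FLT3-ITD main effect, 2 of 35 gave as many lists as the real 14 (highest other 14), and chance cannot be excluded for the lists. Its real count of 0 genes (highest other 3, again the DNMT3A/R882H split) is reached by all 35 and tests nothing. For the DNMT3A/R882H main effect, 35 of 35 gave as many lists as the real 4 (highest other 14), so chance cannot be excluded for the lists. For its genes only 1 of the 35, the real one, gave as many as the real 3 (highest other 0). This is the smallest share these splits can give, and it is not adjusted for the 3 effects tested. Dnmt3a, which rose in the main fit, may be read from the introduced copy and would then follow the real split by design. As 1 such gene would set the real split apart, the splits do not exclude chance for the other genes.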

How the results depend on the processing

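The fits with the arrays of 1 run, the comparison of I with normal marrow, its relation to the deletion and the lists without deleted replicate 3 were chosen after the data were seen, and all other alternatives were planned. Within runs no named gene reversed. Across runs, Hoxa9 in I against vector turned to 0.075 (quantile) and 0.059 (median centring), Dnmt3a in vector against normal to -0.19, -0.28 and -0.17 (quantile, median centring, cyclic loess), Npm1 there to -0.15 and, in NI against I, Idh2 to -0.047 and Dnmt3a to -0.11 (median centring), as the shift between runs was removed. For I against vector, NI against I, vector against normal and AML against normal, in this order, counts were 16824 (83 up), 17213 (17071 up), 17138 (17105 up) and 12689 (11388 up) as deposited, and 5949 (3271 up and 2678 down), 6324 (3769 and 2555), 4108 (1961 and 2147) and 7146 (3941 and 3205) after quantile normalization. They were 8743 (6853 and 1890), 8241 (2644 and 5597), 5628 (1518 and 4110) and 6454 (3378 and 3076) after median centring, 5921 (2961 and 2960), 6216 (3186 and 3030), 4324 (2113 and 2211) and 7144 (3328 and 3816) after cyclic loess, and 10541, 10993, 10907 and 8231 of 13292 genes without the dimmest genes, where fewer genes were tested. The deletion count of 5253 became 8229 (3445 and 4784) with array weights, which gave deleted replicate 3 a weight of 0.138. It became 7390 (3095 and 4295) without deleted replicate 3, and 868 (422 and 446) with its own arrays, the arrays of its run. NI against vector (1089) became 2026 (822 and 1204) with every probe set, 3737 (2402 and 1335) with weights, 2028 (1214 and 814) with the block, 2642 (1488 and 1154) with own arrays and 2923 (1737 and 1186) with its run. I against normal (1030) became 2032 with the block and 429 (116 and 313) with own arrays or its run. FLT3-ITD (0) became 4 with weights and 2 with the block, and the interaction (0) became 5 and 2. DNMT3A/R882H (4) became 7 with median centring, 64 with weights, 27 with the block and 29 with its run, and NIDF against NI (8) became 13 with quantile normalization, 42 with weights, 46 with the block, 0 with own arrays and 41 with its run. With an estimated correlation the lists past camera dropped from 16 to 1 for the deletion and to 0 from 16 for NI against vector, 14 for FLT3-ITD, 5 for DNMT3A/R882H, 9 for the interaction, 12 for NIDF against NI and 12 for I against normal. DNMT3A/R882H had 8 lists with quantile normalization and 8 with median centring. The relation of the deletion to I against vector (r = -0.17) became -0.190 without dim genes and -0.190 with the block, and that to I against normal (-0.24) became -0.193 with every probe set and -0.256 with weights. Leaving out 1 array gave 2990 to 7390 genes for the deletion, 259 to 404 for NI against vector, 170 to 940 for I against normal, 0 to 9 for FLT3-ITD, 3 to 37 for DNMT3A/R882H, 0 to 13 for the interaction and 4 to 48 for NIDF against NI, and across runs 15249 to 15752, 15936 to 16294, 15382 to 16296 and 9831 to 11240. Lists ranged from 14 to 16, 15 to 16, 11 to 13, 11 to 15, 5 to 10 (without NID replicate 1), 8 to 16 (without NIF replicate 2) and 8 to 14 in the order of the first 7 counts, and r from -0.207 to -0.123 and -0.259 to -0.208. Of named-gene values on deletion, 927 kept their side of the threshold under the other settings, 89 lost it and 1 gained it, against 873, 8 and 93 for NI against vector and 716, 51 and 31 for I against normal. Without 1 array 35 were lost for the deletion and 99 each for the other 2. Apart from fewer arrays or genes and the removed shift, the cause was not tested. Over 72 pairs, replicates of like number in different groups correlated at -0.43 to 0.35, with 14 over 0.1. Between groups of 2 arrays both replicates give the same r, so these pairs repeat values. On these values the numbers do not pair the samples, and the block is reported only as a setting. Signal over background limits what can be read of genes near the lowest log2 value of 4.34. Not run were alternatives for linear values, since the values were log2, and other probe sets of Hoxa9 and Meis1, which have 1 each.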

Other observations

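The tests of explanations in this part were chosen only after the results were seen. Genes that moved alike in I against normal and in NI against vector marrow formed a pattern that the lists cover in part. The 112 shared rises included 3 hypoxia genes (Egln3 at 1.09 and 1.31, Bnip3 at 0.81 and 1.15, P4ha1 at 1.15 and 0.89). Of these 3, only Egln3 also passed in I against normal with the own arrays alone. Other shared rises included the glycolysis genes Pfkl, Pfkp and Pgam1, the myeloid transcription factor Cebpa at 0.66 and 0.65, and the stress genes Atf3 and Nr4a1. The 135 shared falls included 6 macrophage genes, the complement genes C1qa, C1qb and C1qc, the receptors Axl and Mrc1, and Vcam1 at -2.39 and -2.37. Mertk, a receptor for dying cells related to Axl and outside the lists, was at -1.75 and -1.48 and is named after its values were seen. On deletion of IDH2/R140Q in leukaemia, Axl rose by 2.60, Vcam1 by 2.91, C1qc by 2.88 and Mertk by 2.23, while Egln3 fell by 1.19, Cebpa fell by 0.70, and Bnip3 and P4ha1 were at -0.04 and -0.06 without passing.

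On the brighter of its 2 probe sets, Mecom had far higher levels in AML than in the marrow groups, a difference for which no test is given. It averaged 10.33 ± 0.03 (SD, n = 2) in AML and 8.04 ± 0.39 (n = 3) in IDH2-deleted AML, against 5.75 in normal marrow, 6.57 in vector and 6.54 to 7.04 in the groups with NPMc. Flt3 averaged 7.94 ± 0.15 in AML and 8.52 ± 1.34 in IDH2-deleted AML, against 8.93 in normal marrow and 9.10 to 9.95 in the groups with NPMc, and it did not pass in AML against normal (-0.99, adjusted p = 0.12). These levels come from different normalization runs.

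Genes of other marrow cells rose on deletion while leukaemia genes fell, and marrow mixed in with its cell types in the proportions of the normal arrays was tested under quantile normalization, median centring and cyclic loess. B-lineage, erythroid and monocyte genes needed unlike shares of normal marrow (medians of 0.34, 0.019 and 1.08 in deleted replicate 2 and 0.70, 0.16 and 1.53 in replicate 3, quantile). Quartiles lay apart between B-lineage and erythroid genes in these 2 arrays, and between monocyte and B-lineage genes in 3 of 3, under each scaling. For stromal genes the lower quartile lay above every AML and normal array in 2 of 3 arrays (replicates 1 and 3). These values argue against such mixing for these lists only as far as rescaling makes the runs comparable. The normal arrays come from another run, and a run effect on single probe sets would change the shares and was not tested. T and NK genes lay above the AML and normal arrays in this way in 1 of 3 (replicate 1, median excess 1.19, against 0.43 and 0.14 in replicates 2 and 3, quantile). For them such mixing cannot be told apart from other explanations. For every list, cells mixed in at other proportions, such as stroma carried over at collection, and a change of the leukaemia cells themselves were not tested. Fewer leukaemia cells per sample would lower genes 4-fold higher in AML than in normal marrow. The falls would be alike and in 1 direction if the cells mixed in hardly expressed these genes. Of these 57 genes, 53 were lower (median -1.40, which the falls of Meis1 and Kit, 1.61 and 1.68 as deposited, lie close to). Their changes spanned 1.92 from the 10th to the 90th percentile (-2.28 to -0.35, against 0.376 between the AML arrays). Between deleted replicates 3 and 1, 23 were lower and 9 higher by over 0.5 (0 and 0 between the AML arrays). The width and the 9 argue against dilution as the whole cause only for cells that hardly express these genes. Cells mixed in at other proportions could express some of them, so dilution as the whole cause is not excluded. A part of it in the falls, those of Meis1 and Kit included, stays open beside an effect of IDH2/R140Q.

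The rise of Hoxa genes in NI against vector marrow was set against 3 explanations. Against a larger share of stem and progenitor cells, the 21 stem genes outside the Hox lists had a median of 0.06. The highest was Kit at 0.51, far below the median of the 5 Hoxa rises (1.65) and just below the lowest (0.57). A general rise of stem genes was thus not seen. These 5 Hoxa genes were those past the threshold, and genes need not move alike with a cell share. The sizes therefore do not exclude this explanation for part of the rise. Loss of B-lineage cells, which would raise the share of all remaining cells, stays open for part of the rise: primary granule genes had a median of 0.27, and the highest, Gfi1 at 0.74, lies above the lowest Hoxa rise. A difference of donor animals, whose sex the labels do not give, cannot be told apart from the genotype, with the Y-linked Eif2s3y at -4.32. An effect of NPMc with IDH2/R140Q on the Hoxa cluster therefore stays a hypothesis.

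A candidate explanation for the genes shared by I and NI marrow is IDH2/R140Q, which both groups carry. Of the 112 shared rises, 34 fell on deletion, where independent calls give 16.4, and 17 rose (13.1). Of the 135 shared falls, 60 rose on deletion (15.8) and 4 fell (19.8). These shares, 30.4% and 44.4%, lay between those for genes called in only 1 of the comparisons (33.2% in I and 26.8% in NI for rises, 27.2% and 48.2% for falls). The differences were not tested. IDH2/R140Q as the shared cause therefore cannot be told apart from other explanations, such as a change in the mix of cells. A difference of donor animals also stays open, since Y-linked genes were lower in both comparisons. Eif2s3y was at -4.32 in NI against vector, and I replicate 1 had 5.20 against a mean of 10.26 in normal marrow. I replicate 2, at 10.44, was not lower. Infection and handling could account for the I part: after quantile normalization the median in vector against normal marrow was -0.018 for the shared rises and -0.25 for the shared falls, against 0.48 and -0.82 in I against normal, but the groups come from different runs, so this explanation cannot be told apart from the genotype.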
